A study of Mus musculus with 3 samples.

How the data were processed

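The series holds 3 sequencing libraries of RNA recovered by immunoprecipitation (RIP-seq) from K7M2 cells, a mouse osteosarcoma line. Per the labels, the cells' own ezrin gene had been knocked out and the cells carried a T567A ezrin transgene, so every library comes from the same genotype. Anti-ezrin antibody gave 2 libraries (replicates 1 and 2) and normal mouse IgG gave 1 library. The labels describe a commercial RIP kit, depletion of ribosomal RNA and paired reads of 150 bases with 6 G of raw data planned per library. They also name polyA RNA as the molecule, and which of the 2 descriptions holds for these libraries was not settled. The labels do not say whether the ezrin libraries came from separate cultures, so edgeR's p-values rest only on the spread between these samples, pooled over genes, which may be technical.

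For each library the authors deposited raw counts per gene symbol and a second table of RPKM, which is the count divided by gene length and by a read total. Per the submitters' processing notes the genome build was GRCm38. The aligner, the counter, the annotation, the use of strand and the treatment of reads that match several places are not given in the sources used here. Deposited count over RPKM gave each gene's length up to 1 factor per library. That factor was set on snoRNA, snRNA and miRNA genes of known length, of which 40 of 49, 35 of 39 and 38 of 46 with a count lay within 0.1% of the median. The read totals implied for the RPKM, in units of 1e6 reads, were 23.9, 19.5 and 14.7 for ezrin replicate 1, ezrin replicate 2 and IgG. Counts assigned to genes made up 82.3%, 83.2% and 68.7% of those totals.

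The tables hold 41743 symbols, of which 17575 had a count in at least 1 library. Of all symbols, 30216 matched a RefSeq gene table of GRCm38.p6, which supplied biotypes, coordinates and older symbols. No sequence was used, so GC content and coding or untranslated parts were not analysed here.

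The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM normalization, the default filterByExpr by group, and Benjamini-Hochberg adjustment at 0.05. It kept 12478 genes. The fit has 1 residual degree of freedom, from the 2 ezrin libraries, moderated across genes, and the single IgG library is assumed to vary like them. The prior degrees of freedom were infinite for every gene, so edgeR used the spread pooled over genes in place of each gene's own. Standard errors (SE) of log2 folds were taken as the size of the fold over the square root of the F statistic and are approximate. CPM are counts per 1e6 counts, scaled by the TMM factors (1.02, 1.04 and 0.946), and values are the mean ± SD of the 2 ezrin libraries against the 1 IgG value. Ratios of a single ezrin library to IgG add 1 CPM to both sides. On simulated counts with 200 changed genes in each of 10 sets of 12478 genes, edgeR called 99.4% of genes raised 4-fold and 95.6% of genes lowered 4-fold. It called 65.4% and 60.4% of those changed 2-fold, and 8.4 unchanged genes per set. The changed genes were drawn from those with a mean of at least 50 counts, and IgG was simulated with the spread of the fit. Only 200 genes changed per set, evenly in both directions, whereas 4548 of 12478 genes were called in the data. These rates therefore do not cover rarer genes, an IgG library that varies more, or the effect of so many differences on normalization and adjustment.

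Before the data were examined, 25 gene lists, the main tests and the rule for named genes were fixed. The comparison of biotypes and the trend with expression level were added after the results were seen. That rule took Ezr, Rdx and Msn, the 10 highest and 10 lowest log2 folds among called genes with a mean of at least 10 CPM and both ezrin libraries on the same side of IgG, the 3 most abundant members and called members of each list, and the 5 most abundant genes of each group. Some genes that the rule takes are not reported. The 18 lists with at least 5 measured members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. They were tested again with a correlation estimated per list and with fry. The estimated version rests on the 1 residual degree of freedom, so it could hardly call any list here. For glycolysis the estimated correlation (−0.0421) was below the preset, yet camera's unadjusted p went from 6.46e-09 to 0.0997. The preset version compares genes within the 1 contrast, so its p-values do not measure the spread between libraries. Each list's median was also placed among 10000 random lists of the same size matched on mean expression. The agreement of the 2 ezrin libraries was set against 100 simulations of 3 libraries of 1 group that share a control. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

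Alternatives to the filter, the normalization, the tool (DESeq2 1.42.0, limma on log2 of RPKM with 1 added), the pseudocount, the fold and the replicates were tried. Further alternatives were chosen after seeing the data: limma-voom, cyclic loess on expression level, a test against a fold of 1.5, and list medians after an expression trend, after cyclic loess or from RPKM.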

Results

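Ezrin ties the plasma membrane to actin filaments, and phosphorylation at the threonine replaced by alanine in T567A opens the protein. T567A ezrin is therefore a form that stays closed, and RNA was recovered with an antibody to it from K7M2 cells, a mouse osteosarcoma line that metastasizes to the lung. The study asked which RNAs closed ezrin binds. The measurement was RIP-seq, with 2 ezrin libraries and 1 IgG library that serves as the background. Counts totalled 19676595 and 16196329 in ezrin replicates 1 and 2 and 10124580 in the IgG library. The number of genes with at least 1 count was 15353, 15123 and 15311 in the same order, and 11944, 11738 and 11821 had at least 10.

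The libraries differed in the kinds of RNA they held. Transcripts of protein-coding genes made up 97.0% (95% interval 97.0 to 97.1) and 97.5% (97.5 to 97.6) of counts in the ezrin libraries and 74.1% (74.1 to 74.1) in the IgG library. Remnants of ribosomal RNA, mainly reads at Gm26917 and Gm42418, held 0.125% (0.123 to 0.127) and 0.201% (0.199 to 0.203) against 16.5% (16.4 to 16.5) in IgG. Small structured RNAs such as 7SL and RNase P RNA held 1.09% (1.08 to 1.09) and 0.523% (0.519 to 0.527) against 6.51% (6.50 to 6.53). Mitochondrially encoded genes held 0.0120% (0.0116 to 0.0125) and 0.0163% (0.0157 to 0.0170) against 0.358% (0.354 to 0.361), and replication-dependent histones held 0.617% (0.614 to 0.621) and 0.553% (0.550 to 0.557) against 1.72% (1.71 to 1.72). Messages of cytosolic ribosomal proteins took similar shares of all counts, 3.17% (3.16 to 3.18), 3.05% (3.04 to 3.06) and 2.97% (2.96 to 2.98). Because protein-coding genes held less of the IgG counts, the share of ribosomal proteins among protein-coding counts was larger in IgG than in the ezrin libraries.

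**Figure D1:**
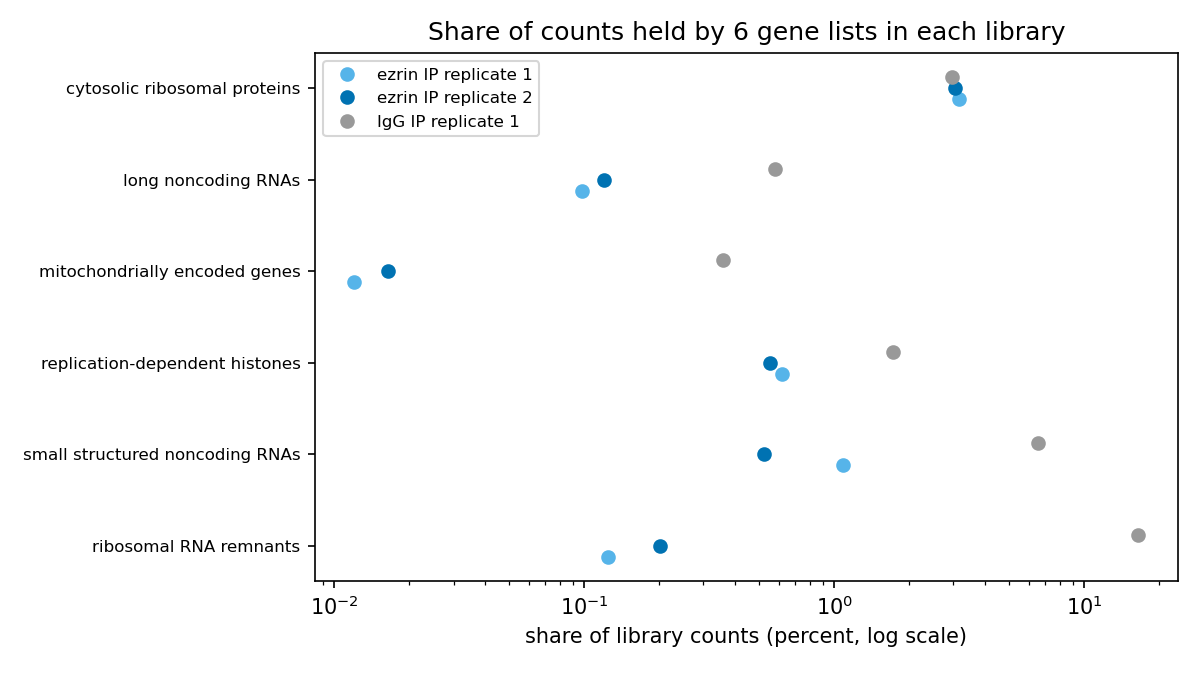
Share of all counts in each library (percent, log scale) held by 6 gene lists; each point is 1 library. Ribosomal RNA remnants lie at 16.5% in the IgG library and at 0.125% and 0.201% in the ezrin libraries, while ribosomal protein messages lie near 3% in all 3.

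Compared with IgG, the ezrin libraries were richer in many messages of RNA helicases and stress granule proteins, glycolytic enzymes and cell cycle genes and poorer in mitochondrially encoded, histone and structured noncoding RNAs. Camera called these lists with its preset correlation and called none with an estimated correlation (adjusted p = 0.337 to 0.429). The estimated version has 1 residual degree of freedom and could hardly call any list, so it decides little here. Hnrnpa2b1, which encodes an RNA-binding protein, was 3.93-fold higher, at 1658 ± 348 CPM (SD, n = 2) against 422 CPM. Ezrin's own message, Ezr, was 2.26-fold higher, at 349.7 ± 1.07 against 155 CPM. The mitochondrial message mt-Atp6 was 58.5-fold lower, at 4.56 ± 1.31 against 265 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2377 genes were higher and 2171 lower, and 7930 were not called. Of these calls, 1227 higher and 1190 lower genes changed at least 2-fold, and 107 higher and 449 lower genes at least 4-fold.

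Of the 3 genes of the ezrin family, Ezr and Msn were higher and Rdx was not called. Ezr (chromosome 17, 6738131 to 6782780, GRCm38) had a log2 fold of 1.18 (SE 0.24, edgeR adjusted p = 1.3e-05), and the counts cannot separate the transgene from the gene itself. Msn, which encodes moesin (chromosome X, 96096045 to 96168553), had a log2 fold of 1.46 (SE 0.24, edgeR adjusted p = 3.22e-08). Rdx, which encodes radixin (chromosome 9, 52047150 to 52088738), was at 116 ± 18.2 CPM against 157 CPM and was not called (log2 fold −0.44, SE 0.23, edgeR adjusted p = 0.129), although it passed on the lower side at a mean of at least 10 CPM (adjusted p = 0.0351) and after cyclic loess (adjusted p = 0.0341). Within the list of 14 family members and partners, 3 were higher and 6 lower, the same counts as when adjusted over the list alone. The lower ones included the hyaluronan receptor Cd44 (log2 fold −1.12), the kinase Rock1 (−1.10), which acts on these proteins, and Nf2 (−0.92), the related protein merlin. The list's median was −0.59, with −0.57 and −0.38 in ezrin replicates 1 and 2 and −0.10 with RPKM, which moved the median of all genes up by 0.35, and camera did not call it (adjusted p = 0.457).

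Among the 10 highest called genes was Avil, an actin-binding protein of the villin family (chromosome 10, 127000065 to 127020994), with a log2 fold of 2.83 (SE 0.39, edgeR adjusted p = 3.27e-11). This group also held Hsd17b4 (2.38), an enzyme of peroxisomal fatty acid oxidation, Gnl2 (2.36), a nucleolar GTPase, the RNA-binding protein Hnrnpa3 (2.34), Ptgr1 (2.27), a prostaglandin reductase, and the small nuclear RNA gene Gm25890 (2.26). Eml2 (2.26), a microtubule-associated protein, Nup107 (2.25), a subunit of the nuclear pore, and Pla2g4a (2.17), a cytosolic phospholipase, were in it too. Among the 10 lowest were Gm26917 (−6.89) and Gm42418 (−6.42), the mitochondrial genes mt-Atp6 (−5.87), mt-Co3 (−5.48), mt-Rnr2 (−5.36), mt-Cytb (−5.34), mt-Nd4 and mt-Nd1, and the short noncoding genes Gm23444 (−5.24) and Gm24447 (−5.09). The most abundant messages of the ezrin libraries were the chaperone Hsp90ab1 (log2 fold 1.78), the elongation factors Eef1a1 (0.87) and Eef2 (1.03), the intermediate filament protein Vim (1.43) and the nonmuscle myosin Myh9 (1.35). In the IgG library they were Gm26917, the 7SL RNAs Rn7s2 (−3.23) and Rn7s1 (−2.52), Gm42418 and the RNase P RNA Rpph1 (−3.78). Rn7s1 differed 18.5-fold between the ezrin libraries (91077 and 4089 counts). Its ratio to IgG was −1.60 in ezrin replicate 1 and −5.81 in ezrin replicate 2 on the log2 scale, and with DESeq2 it did not pass (adjusted p = 0.406). By edgeR it was called with an SE of 0.18, since the pooled spread took the place of its own. Gm26917, Gm42418, 7SL, small nuclear RNA and histone genes have near-identical copies, and how shared reads were counted is not given in the sources used here, so their single values are uncertain.

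**Figure D2:**
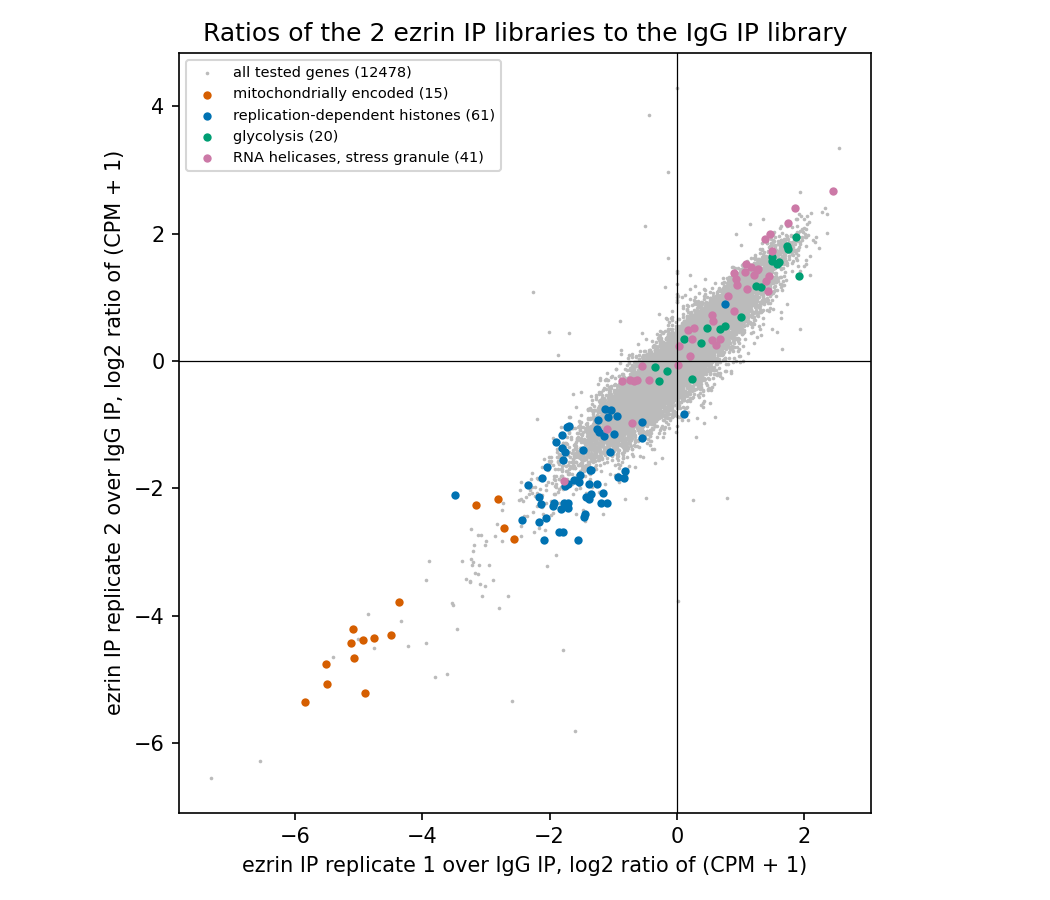
Log2 ratio of CPM (1 added) of ezrin replicate 1 to IgG (x axis) and of ezrin replicate 2 to the same IgG library (y axis), with 1 point per tested gene (12478) and 4 gene lists in colour. Mitochondrially encoded genes and histones lie low on both axes, and most glycolysis and RNA helicase genes lie above 0 on both. The shared IgG library alone pulls the points towards the diagonal.

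RNA made inside mitochondria, histone messages and noncoding RNAs were lower in the ezrin libraries as groups. All 15 measured mitochondrially encoded genes were lower (15 adjusted over the list alone), with a median log2 fold of −4.84 and with mt-Co1, the most abundant, at −4.42. Of 61 replication-dependent histones, 58 were lower and none higher (59 and 1 adjusted over the list alone), among them H4c4 (−2.16) and H2bc8 (−2.47), and the median was −1.75. Of 24 small structured RNAs, 17 were lower and 2 higher (the same adjusted over the list alone), with a median of −3.13. It was −1.86 and −2.31 as a plain ratio in ezrin replicates 1 and 2, and −1.79 with a trend on gene length subtracted. The 7SK RNA Rn7sk (−4.13), the U2 gene Rnu2-10 (−3.97), Scarna2 (−4.44) and Snora73b (−3.18) were among the lower ones. The higher ones were the U1 genes Rnu1b6 (2.06), which DESeq2 left just above the threshold (adjusted p = 0.0519), and Rnu1a1, whose call rested on 22 counts in ezrin replicate 2 alone. Of 24 long noncoding RNAs, 13 were lower and 2 higher (14 and 2 adjusted over the list alone), with a median of −0.88 that shrank to −0.27 with RPKM, a larger move than that of all genes. The nuclear RNAs Malat1 (−4.99), Neat1 (−2.12), Xist (−4.69) and Kcnq1ot1 (−4.92) were lower, and the snoRNA host genes Zfas1 (0.74) and Snhg5 (0.68) higher. Camera called the 4 lists lower, with adjusted p = 1.36e-89, 4.12e-47, 1e-30 and 5.54e-10 in the order given. With an estimated correlation each had an adjusted p = 0.337.

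Across biotypes, 152 of 522 long noncoding RNA genes were lower and 10 higher, against 1774 lower and 2318 higher of 11301 protein-coding genes. The share of lower genes was larger among long noncoding RNAs (odds ratio 2.21, two-sided Fisher's exact test across genes, which are not independent, p = 6.1e-14). The test did not account for expression level, with which the calls also varied. It left out 553 tested genes without a biotype, of which 208 were lower and 36 higher.

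Many messages of RNA helicases and stress granule proteins, and of enzymes that break down glucose, were more abundant in the ezrin libraries. Among 41 RNA helicases and stress granule proteins, 23 were higher and 4 lower (24 and 5 adjusted over the list alone), with a median log2 fold of 0.86. Taf15 (2.17) and Ewsr1 (1.33) were higher, as were Hnrnpa2b1 (1.97) and the helicases Dhx9 (1.68) and Ddx3x (1.34). The lower ones included the mRNA-binding proteins Igf2bp2 (−2.31) and Ybx1 (−0.84) and the microRNA partner Ago2 (−1.09). Igf2bp2 was rare, with 38, 28 and 85 counts in ezrin replicates 1 and 2 and IgG. Of 20 glycolysis genes, 13 were higher and none lower (14 and none adjusted over the list alone), with a median of 1.04. They included Pfkm (1.94), Hk2 (1.80), Hk1 (1.76), Eno1 (1.66) and Pkm (1.58), which reached 4600 ± 137 CPM (SD, n = 2) against 1537 CPM. Camera called both lists higher (adjusted p = 2.87e-08 and 2.33e-08), and with an estimated correlation the adjusted p = 0.429 and 0.337. After cyclic loess the medians shrank to 0.33 and 0.65.

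Lists of cell cycle genes, translation factors and respiratory chain genes were called in the same direction, though 14, 10 and 42 of their members were not called. Of 40 cell cycle genes, 23 were higher and 3 lower (24 and 4 adjusted over the list alone), with a median of 0.72. The replicative helicase subunits Mcm3 and Mcm7 (1.97), the sliding clamp Pcna (1.12) and the mitotic activator Cdc20 (1.51) were higher, and Mki67 (−1.56), Cdk6 (−0.77) and Ccnd2 (−0.68) lower. Of 30 translation factors, 18 were higher and 2 lower (19 and 2 adjusted over the list alone), with a median of 0.66, for example Eif4a1 (1.33) and Eif3c (1.29) against Tpt1 (−1.14). This median lay at percentile 91.3 of expression-matched random lists, inside their 95% range. After cyclic loess it shrank to 0.03 and that of the cell cycle genes to 0.44. Of 72 nuclear-encoded respiratory chain genes, 27 were higher and 3 lower (31 and 3 adjusted over the list alone), with a median of 0.42. Ndufs1 (2.08), Atp5b (1.70) and Sdha (1.51) were higher and Atp5e (−1.27) lower, opposite to the mitochondrially encoded subunits of the same chain. Camera called the 3 lists higher (adjusted p = 1.24e-07, 1.16e-04 and 8.39e-05), and with an estimated correlation each had an adjusted p = 0.337.

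Matrix, secretory and actin genes were also called higher as lists. Of 31 extracellular and bone matrix genes, 15 were higher and 4 lower, the same as adjusted over the list alone, with a median of 0.50. The collagens Col3a1 (1.23) and Col1a2 (1.13) and osteopontin Spp1 (1.14) were higher, and Timp2 (−0.72), Lox (−0.76) and the bone transcription factor Runx2 (−0.73) were lower. Of 34 endoplasmic reticulum chaperones and secretion genes, 10 were higher and 2 lower, also when adjusted over the list alone, with a median of 0.31, for example Hspa5 (1.39) and Pdia6 (1.57). Of 46 actin and focal adhesion genes, 12 were higher and none lower, again the same adjusted over the list alone, with a median of 0.19. Myh9, Actn1 (1.43), Actn4 (1.43) and Tln1 (1.29) led this list, whereas Actb was not called (0.19). Camera called these 3 lists higher (adjusted p = 0.0105, 0.0227 and 0.0105), and with an estimated correlation the adjusted p = 0.683, 0.393 and 0.377. At a mean of at least 10 CPM none of the 3 passed (adjusted p = 0.0565, 0.124 and 0.102). The endoplasmic reticulum and actin medians lay at percentiles 73.3 and 31.0 of expression-matched random lists, inside the range of those lists. After cyclic loess the first shrank to 0.04 and the second turned to −0.04.

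Other lists went both ways, and camera called none of them, although at a mean of at least 10 CPM it called the cytosolic ribosomal proteins lower (adjusted p = 0.0434). Of 79 cytosolic ribosomal protein genes, 6 were higher and 16 lower (5 and 16 adjusted over the list alone), with a median of −0.04 that became 0.08 with library size as the only scaling, which moved all genes by 0.12, and −0.46 after cyclic loess (camera adjusted p = 0.192). This median lay at percentile 0.11 of expression-matched random lists, below their 95% range. Rpl3 (0.81) was higher, and Rps12 (−1.68), Rplp0 (−1.47) and Rpl41 (−1.24) were lower. Of 35 metastasis and mesenchymal transition genes, 8 were higher and 7 lower (9 and 9 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.455). The higher ones included Vim and the matrix proteases Mmp3 (2.30), Mmp9 (1.82) and Mmp13 (1.19), and the lower ones the transcriptional coactivator Yap1 (−0.97). Mmp3 was rare, with 127, 155 and 15 counts in ezrin replicates 1 and 2 and IgG. Of 39 PI3K, mTOR and MAPK signalling genes, 3 were higher and 10 lower, also adjusted over the list alone, with a median of −0.18 (camera adjusted p = 0.151). Mtor (0.94) was higher, and Gsk3b (−1.66) and Braf (−1.06) were lower. Of 40 chromatin regulators with long transcripts, 10 were higher and 7 lower, the same adjusted over the list alone, with a median of −0.11 (camera adjusted p = 0.914), from Smarca4 (1.18) and Chd4 (1.16) to the histone methyltransferase Nsd1 (−4.18). Nsd1 was rare, with 6, 16 and 107 counts in ezrin replicates 1 and 2 and IgG. Of 19 immediate early genes, 4 were higher and 4 lower (5 and 4 adjusted over the list alone), with Junb at 1.09, Jund at −1.28 and Fosb at −3.87. Fosb was rare, with 14, 14 and 108 counts in ezrin replicates 1 and 2 and IgG. The median of the immediate early genes was 0.04 while camera's direction was lower (adjusted p = 0.808). It was 0.11 in ezrin replicate 1 and −0.20 in ezrin replicate 2. Cyclic loess turned the metastasis and immediate early medians to −0.19 and −0.23. RPKM turned the signalling and chromatin medians to 0.16 and 0.25, a rise about equal to that of all genes (0.35). Subtracting a trend on gene length turned the chromatin median to 0.12 and the immediate early median to −0.04. Among expression-matched random lists the ezrin partner, signalling and chromatin medians lay at percentiles 0.15, 1.56 and 1.01, also below the 95% range. In ezrin replicate 2 alone the partner and chromatin lists lay inside it, at percentiles 2.88 and 2.63.

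Markers of other cell types were mostly absent or too few to test. Epithelial and erythroid lists had no measured member. The macrophage list had 3, of which Csf1r reached 917 ± 66.4 CPM against 1234 CPM and was not called (edgeR adjusted p = 0.0945), although it passed on the lower side at a mean of at least 10 CPM (adjusted p = 0.0442) and after cyclic loess (adjusted p = 4.09e-05). The endothelial list had 3, the antibody-producing B cell list had 1 (Sdc1), and none of these was called. Of 3 measured osteoclast markers, Mmp9 was higher. Of 3 measured ribosomal RNA remnants, Gm26917 and Gm42418 were lower, and Lars2, a protein-coding gene placed in that list, was not called.

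**Figure D3:**
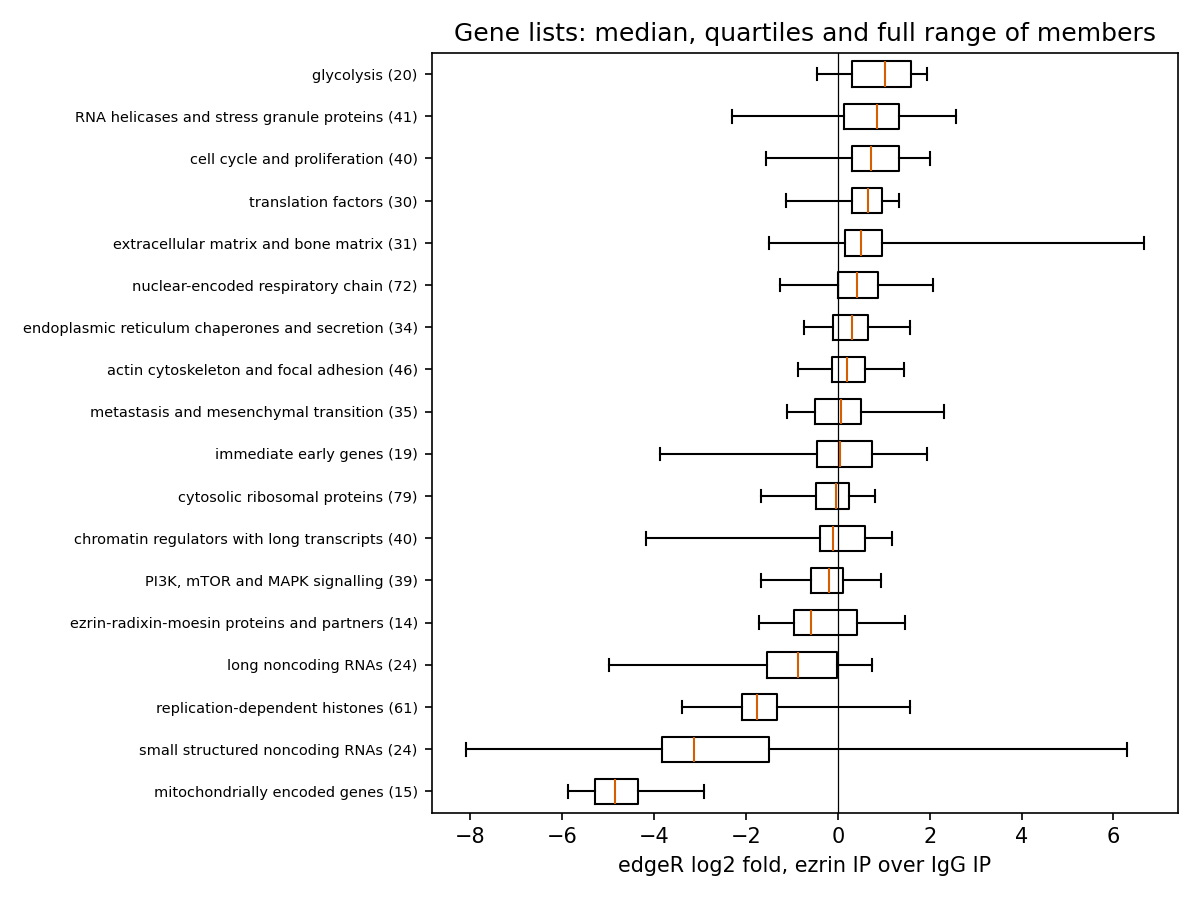
Median (line), quartiles (box) and full range (whiskers) of the edgeR log2 fold, ezrin over IgG, for the 18 lists with at least 5 measured members, with the number measured in parentheses. Medians run from −4.84 for mitochondrially encoded genes to 1.04 for glycolysis.

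Abundant messages depended on how expression level was treated. After cyclic loess, Eef1a1, Eef2, Vim, Myh9, Col1a2, Gapdh and Rpl3 no longer passed (adjusted p between 0.144 and 0.937). The less abundant Zfas1 and Snhg5 also lost their calls (adjusted p = 0.0809 and 0.104), with log2 folds of 0.58 in both. With DESeq2, Runx2 and Snhg5 did not pass (adjusted p = 0.0519 and 0.108). With limma on RPKM, the lower calls of Rock1, Nf2, Ybx1, Cdk6, Ccnd2, Timp2, Lox, Runx2, Yap1 and Braf ended (adjusted p between 0.073 and 0.344), and so did that of Rn7s1 (adjusted p = 0.0751).

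The balance of higher and lower calls also depended on scaling, filter and tool. Of the edgeR calls, 52.3% were higher, against 62.0% with library size only, 53.2% with the size factors of DESeq2 and 49.6% at a mean of at least 10 CPM. Limma-voom with TMM gave 50.6%. Alternatives that change tool and scaling together gave 61.3% (DESeq2 with its own size factors), 79.5% (limma on RPKM) and 45.8% (cyclic loess). Scaling by library size moved the median log2 fold of all genes by 0.12 and RPKM moved it by 0.35, so the folds given here are relative to TMM.

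Read as a plain ratio, 849 genes were at least 2-fold above IgG in both ezrin libraries and 763 at least 2-fold below it. With RPKM the counts were 1348 and 175, and with 5 CPM added in place of 1 the lower count was 326, so their balance depends on the unit. Taf15 stood 1.86 and 2.41 above IgG on the log2 scale in ezrin replicates 1 and 2. Malat1 stood at −5.40 and −4.65, and H2bc8 at −2.43 and −2.49. With ezrin replicate 1 in the place of IgG, 12 genes parted from both other libraries by that margin, and with ezrin replicate 2 in its place 44 did, against 1612 for IgG.

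The ezrin libraries resembled each other more than either resembled IgG. Across 8604 genes with a mean of at least 10 CPM, log2 CPM correlated at r = 0.983 between them and at 0.867 and 0.861 with IgG. The SD of the log2 ratio of one to the other was 0.285 over 8482 genes, against 0.732 for their mean over IgG. They were not the same library, as chi-square per degree of freedom was 30.4 over 11815 genes. The log2 ratios of the 2 libraries to IgG correlated across genes at r = 0.917, where sharing the IgG library alone gave 0.537 on average and at most 0.554 in 100 simulations. The covariance was 0.571 against a simulated 0.0565, a difference of 0.514, and 86.9% of genes lay on the same side of IgG in both against a simulated 67.8%. The simulation covers the spread between replicates but not features of this 1 IgG library, which enter both ratios.

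Long genes were slightly less represented in the ezrin libraries, a weaker trend with length than that between the ezrin libraries themselves. In the longest 20% of genes, with gene models of at least 7541 bases, the median log2 fold was −0.17, and in the other 4 groups of equal size it lay between −0.02 and 0.07. Long-transcript genes went both ways there, such as Dhx9 (gene model of 9603 bases, 1.68) and Gsk3b (9831 bases, −1.66). Spearman's rho across 12478 genes, which are not independent replicates, was −0.0512 and ranged from −0.0911 in ezrin replicate 1 to −0.0154 in ezrin replicate 2. It was −0.139 at a mean of at least 10 CPM. For the ratio of ezrin replicate 1 to ezrin replicate 2, rho with length was −0.188, so the trend over IgG is no firm feature of the ezrin libraries. Expression level ordered the ratios more (rho = 0.266), and the median log2 fold was −0.54 in the least abundant 20% of genes and 0.28 in the most abundant 20%.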

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

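No paired analysis was possible because the 2 groups share only replicate number 1. The tests with limma-voom, cyclic loess, a fold threshold of 1.5 and an expression trend were chosen after seeing the data. Against edgeR's count of 2377 higher and 2171 lower genes, DESeq2 gave 1747 and 1101, limma on RPKM 3734 and 964, and testing against a fold of 1.5 gave 987 and 896. The other 7 alternatives with a test stayed within 1.5 times. Of the 4548 calls, 2848 kept their direction and call with DESeq2, 3243 with RPKM, 3290 with cyclic loess and 3951 with limma-voom; the smaller count at a fold of 1.5 follows from its threshold, and the cause of the others was not tested. The counts of 849 and 763 genes at 2-fold in both ezrin libraries became 2102 and 2021 at 1.5-fold, 11 and 96 at 4-fold, 1348 and 175 with RPKM, and the lower count became 326 with 5 CPM added and 503 at a mean of at least 10 CPM. With 1 ezrin library left out they ranged from 1095 to 1132 higher and 1074 to 1106 lower. Camera's 8 higher and 4 lower lists became 0 and 0 with an estimated correlation and 0 and 0 with fry; at an unadjusted p under 0.05 the first called 0 lists and fry 3. At a mean of at least 10 CPM they were 5 and 5, with 3 higher calls lost and the ribosomal proteins gained as lower. The correlation of the ratios, 0.917, was 0.934 at that minimum, 0.932 with 5 CPM added and 0.921 with RPKM. The rho with length was −0.139 at that minimum and between −0.0911 and −0.0154 with 1 ezrin library left out. After cyclic loess the log2 folds of Eef1a1 (−0.18), Rpl4 (−0.10), Pabpc1 (−0.24), Tuba1b (−0.0330) and Pgam1 (−0.0655) turned negative without passing, and Actb (−0.72), Ccn1 (−0.63), Calr (−0.70) and Ccnd1 (−0.56) turned negative and passed. The actin list's median turned to −0.04 after cyclic loess (−0.0387) and after the expression trend (−0.0435). Of 181 named genes, 149 kept direction and side with cyclic loess, 154 with RPKM, 166 with DESeq2, 142 against a fold of 1.5 and 176 with library size only. A floor of 3 counts corresponds to 0.296 CPM in the IgG library, and the least abundant 20% of genes held the fewest higher calls (3.97%) and the most lower calls (19.95%).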

Other observations

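The tests in this part were chosen after the results were seen. Families of genes that share a name were looked at next, 31 in all, of which 29 had at least 5 measured members. Camera with its preset correlation called 16 higher and 6 lower after adjustment over the 29. With an estimated correlation it called 0, which the 1 residual degree of freedom made nearly certain. The groups below were redrawn from 9 of these names, so they were picked for what they showed, and camera p-values below are those of the names over the 29. The Cct name covered 8 genes with 7 higher, names ending in ars 17 with 16 higher and Mcm 11 with 9 higher, so these differ in part from the groups described. Subunits of several large complexes were among the higher ones. All 8 subunits of the CCT chaperonin, which folds actin and tubulin, were called higher, with a median log2 fold of 1.39 and Cct3 at 1.77 (camera adjusted p = 1.87e-07 for the Cct name, and adjusted p = 0.373 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 19 were higher and none lower, led by Hars (2.13) and Tars (2.01), with a median of 1.51 (camera adjusted p = 3.79e-16 for names ending in ars, and adjusted p = 0.373 with an estimated correlation). All 6 subunits of the MCM helicase were higher, with a median of 1.48 (camera adjusted p = 6.89e-08 for the Mcm name, and adjusted p = 0.373 with an estimated correlation). These subunits also belong to the fixed cell cycle list, so they add no separate evidence to it. Of 39 proteasome subunits, 28 were higher and 1 lower (Psmd11, which did not pass with DESeq2, adjusted p = 0.0795), with a median of 0.99, for example Psmd2 (1.63) (camera adjusted p = 2.92e-12, and adjusted p = 0.373 with an estimated correlation). Of 20 hnRNP genes, 17 were higher and 1 lower (Hnrnpul1, −0.84, not passing with limma on RPKM, adjusted p = 0.115), with a median of 1.13 and Hnrnpm at 2.02 (camera adjusted p = 1.32e-11, and adjusted p = 0.413 with an estimated correlation). Some of them, such as Hnrnpa2b1, also belong to the fixed list of RNA helicases and stress granule proteins. Of 15 aldehyde dehydrogenases, 11 were higher and none lower, with a median of 1.22 and Aldh2 at 2.03 (camera adjusted p = 2.17e-05, and adjusted p = 0.373 with an estimated correlation). These 6 medians stayed above 0 under each scaling tried.

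Genes for membrane proteins went the other way relative to the rest. Of 185 solute carriers, 13 were higher, 51 lower and 121 not called, with a median of −0.34. Of 146 numbered Tmem genes 8 were higher, 31 lower and 107 not called, with a median of −0.33. Over all 12478 tested genes, 2377 were higher and 2171 lower. Slc39a1 (−1.20), a zinc transporter, and Tmem65 (−1.28) were examples. With RPKM both medians lay near 0 (0.01 and 0.04), a rise about equal to the 0.35 by which RPKM moved the median of all genes, so their place relative to other genes was kept. Camera called the Slc and Tmem names lower (adjusted p = 0.0112 and 0.0263), and with an estimated correlation the adjusted p = 0.376 and 0.373. Within the solute carriers, 9 of 37 mitochondrial Slc25 genes were higher and 10 lower, with Slc25a4 (1.25) and Slc25a5 (1.18) on the higher side, and their median of −0.11 was compared with −0.41 in the other 148 genes. That difference did not pass (two-sided permutation test across genes, 10000 draws, p = 0.0713). Of 314 numbered zinc finger genes, 17 were higher and 62 lower, with a median of −0.23, and camera over all 29 families left the Zfp group above the threshold (adjusted p = 0.0565).

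Mitochondrially encoded, small noncoding and histone RNAs were lower together in the ezrin libraries. Nuclear RNA in the IgG library would not cover the whole pattern. The mitochondrial mRNAs and the 7SL RNAs, which are not nuclear, had a median of −4.80. They are part of the pattern and were taken after it was seen, so this restates it and is no separate test. The 7SL RNAs alone were at −3.23 (Rn7s2) and −2.52 (Rn7s1), and Rn7s1 differed 18.5-fold between the ezrin libraries. Whether an excess belongs to IgG immunoprecipitation or to this 1 IgG library cannot be told apart, because the number of IgG libraries is 1. The ratios also cannot tell an excess in IgG from a loss in the ezrin libraries. Whether polyA RNA or depletion of ribosomal RNA was used was not settled, and a difference in preparation was not tested. No biological explanation was tested, since all libraries share a genotype.

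Subunits of cytosolic complexes (67 genes of the CCT, proteasome and synthetase families) and the 331 solute carrier and Tmem genes differed in median log2 fold by 1.52 (95% bootstrap interval over genes 1.27 to 1.71). After a smooth trend on expression level and gene length was subtracted the difference was 0.987 (0.871 to 1.19), so the fitted trend took up only part of it. The remainder decides nothing about the cause, because the families were picked for showing the difference. Both intervals treat genes as independent. A lower yield of all mRNAs translated at the endoplasmic reticulum is argued against by the extracellular matrix list, whose median was 0.50 (15 of 31 higher, 4 lower). That list also holds transcription factors such as Runx2, and camera did not call it at a mean of at least 10 CPM (adjusted p = 0.0565). A loss limited to some of these mRNAs was not tested. The nuclear MCM helicase and hnRNP genes were higher too, so the contrast is not one of cytosolic proteins alone. The families were picked because they showed it, its cause stays open, and no biological explanation was tested.

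Small nuclear RNA genes split by length. Of 10 tested genes of 164 to 166 bases, the length of U1, 7 were higher and 0 lower, and of 10 tested genes of 191 bases, the length of U2, 9 were lower and 0 higher. Among the 7, Rnu1a1 rested on 22 counts in ezrin replicate 2 alone, and Rnu1b6 did not pass with DESeq2 (adjusted p = 0.0519). Reads moved between near-identical copies are argued against as the whole cause, because the summed classes still differed by 5.06 on the log2 scale in the ezrin library with the smaller difference (5974, 4702 and 888 counts against 824, 491 and 4096 in ezrin replicates 1 and 2 and IgG). The class of U1 length lay at least 1.59 above IgG in both ezrin libraries, so not all short RNAs were lower. This restates the split and is no separate test of a cause. Other RNAs rose as much, such as Cct3 (1.77), and 1227 called genes were at least 2-fold higher. Retention of U1 with the ezrin immunoprecipitate was not tested and may at most be a hypothesis to follow up, with no second IgG library to test it.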
